A study of Mus musculus with 91 samples.

How the data were processed

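Total liver RNA of 91 male mice was extracted with Qiazol, labelled with biotin by the 3'IVT Express kit and measured on Affymetrix mouse arrays, per the labels' protocols. Livers were taken at necropsy, rinsed and frozen. The deposited values are log2 expression values per probe set made by the authors with RMA, per the submitters' processing notes, which corrects background, equalises the distributions of the arrays and summarises the probes of a set. The software and version of RMA were not given in the sources used here, nor was a genome build. The deposited table held 45037 probe sets in 91 columns, each matched to 1 sample, with no control probe sets, so that RNA quality could not be read from 3' to 5' ratios. Values ranged from 2.61 to 15.34 and array medians from 5.18 to 5.36, as in arrays normalised together. Because RMA equalises the distributions, a change in total RNA per cell would not be seen, and large folds are compressed near the lower and upper ends of the scale, where Cyp3a11 lies in treated and control livers alike.

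Probe sets were named from the table supplied with the platform. A single gene symbol was given for 34945 probe sets, several symbols for 932, and 9160 were unnamed here and not used. Each gene was represented by its single-symbol probe set with the highest mean over all arrays, which gave 18193 genes, of which 9010 had more than 1 probe set. Members of gene families with close sequences, such as Cyp2b, Cyp2c, Cyp3a, Cyp4a, Gstm and Saa, may share signal across probe sets, so that their single members are uncertain.

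Groups, doses, times and the control of each treated group came from the labels. The titles of all 5 arrays of 28 days of phenobarbital end in "(2)", whose meaning is not given in the sources used here, so that a repeat of the arrays or of the dosing cannot be excluded for the values at 28 days and for the comparison with 56 days. The series states that mice were assigned at random to groups of 5, so replicates were taken as separate mice. A means model with 1 coefficient per group was fitted to all 91 arrays in 19 groups, with 72 residual degrees of freedom, with limma 3.58.1 in R 4.3.3. Contrasts were treated minus the named control, and differences of such contrasts for the strains given CITCO, the times of phenobarbital, and Wy-14643 against pioglitazone. Moderated tests with a mean-variance trend were two-sided and adjusted by Benjamini and Hochberg over the 18193 genes of each comparison. A gene passed at an adjusted p below 0.05, and genes changed at least 2-fold are counted beside that. Replicate numbers did not pair the mice, so they were not used as a block in the model.

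Of 770 members of 35 gene lists, 680 were measured. They cover nuclear receptor targets, stress responses, proliferation, metabolism, sex-biased and zonated genes, inflammation, time of day, tumour-associated genes, and markers of other cell types of the liver. The 34 lists with at least 5 measured members were tested in 10 comparisons, 340 tests in all, with camera and a preset correlation between genes of 0.01, adjusted over all tests, and 132 passed. With the correlation estimated for each list 23 of these passed, and with camera on ranks 131 lists passed in all. A test of direction with fry, which asks whether the genes of a list move one way and does not compare them with other genes, passed 46 times, and its mixed version, for changes either way, 24 times. Lists that pass with an estimated correlation are named as such beside each result. Members were also tested with p-values adjusted over the list alone.

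The gene lists, the rule for the genes named in the text and the other settings to try were fixed before the data were examined. They are the 5 largest rises and falls past the threshold with all treated values outside the control range, clone names passed over, 17 measured genes of 18 fixed in advance, up to 4 members with the largest change of each list described, and Nr1i3 and Nr1i2 between strains. Some members of the lists, such as Cyp4a10, were not measured by a probe set with a single symbol named here.

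The procedure was tested on simulated values, drawn once, with 18193 genes and 200 changed genes per comparison. Each gene had 1 spread, pooled over all real groups. Real groups differed in spread, as in Cyp2b10 after piperonyl butoxide (SD 2.55) and in its controls (SD 0.405), which the simulation leaves out. Differences between the shares of single comparisons include the chance of the draw and do not rank the comparisons. For CITCO in C57BL mice 40.3% of genes changed by 0.5 on the log2 scale and 95.5% of those changed by 1 were recovered, with 7.6% of calls false. For CITCO in hCAR/hPXR mice the shares were 74.6% and 95.5%, for phenobarbital 52.2% and 95.5% at 28 days and 44.8% and 98.5% at 56 days. They were 61.2% and 97% for cyproterone acetate, 58.2% and 100% for 1,4-dichlorobenzene, 52.2% and 95.5% for piperonyl butoxide, 49.3% and 95.5% for Wy-14643, 46.3% and 95.5% for pioglitazone and 50.7% and 97% for methapyrilene. A shift of 0.5 put into the cholesterol synthesis list in the Wy-14643 comparison was called, with 2 calls in 340 tests. The simulated genes were drawn independently of each other, unlike the genes of the real lists. The number of list calls here therefore does not show how often the preset correlation gives false calls in the real data.

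Correlations of fold changes across genes are descriptions and carry a jackknife SE from leaving out single arrays and no p. Because cyproterone acetate and 1,4-dichlorobenzene share the corn oil controls, 100 pairs of unchanged groups were simulated, each pair with a simulated control group in common. The real corn oil controls were also split into groups of 2 and 3. The overlap of calls was set beside that of independent lists where the controls differed. Alternatives covered the arrays in the fit, the probe sets per gene, a filter on low values, the variance trend, array quality weights, repeated normalisation, median centring, the replicate number as a block, all CMC cohorts pooled as the control, and each array left out in turn. Removing the 5 arrays with a quality weight below 0.4 was added after seeing the data. For each count of genes and for the list calls 100 splits of the compared arrays into groups of the same sizes, the real one included, were refitted. No sample was left out.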

Results

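Liver RNA from 91 adult male mice was measured on Affymetrix expression arrays, with 1 array per mouse. Most mice were C57BL, and 10 were hCAR/hPXR mice, in which the mouse nuclear receptors CAR and PXR are replaced by their human counterparts. The mice formed 19 groups of 5, apart from the groups given piperonyl butoxide and 3 of the carboxymethylcellulose (CMC) control cohorts, named Co1, Co3 and Co5 in the labels, which held 4 each. Compounds were given for 28 days, and phenobarbital also for 56 days, and each treated group had a control group named in its labels. The chemicals include activators of CAR, PXR and the peroxisome proliferator-activated receptors (PPARs), as well as methapyrilene, a liver carcinogen best known from rats. The deposited log2 values covered 45037 probe sets and ranged from 2.61 to 15.34, with array medians between 5.18 and 5.36. The number of arrays per group limits the precision of each value. In each comparison 18193 genes were tested with limma, each by 1 probe set, and a gene was counted as changed at an adjusted p below 0.05. Some of the gene lists described below share members, such as Gstm3 and Abcc4 in the lists of CAR and NRF2 targets. Each list described, apart from the aryl hydrocarbon receptor targets, passed the camera test with a preset correlation between genes, and the outcome with an estimated correlation is given beside it. Values after a gene name are log2 fold changes, treated minus control, with their standard errors.

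The mouse genes replaced in the hCAR/hPXR mice were compared first, in untreated livers. Nr1i3, the gene of mouse CAR, had a mean log2 value of 5.86 ± 0.378 (SD, n = 5) in hCAR/hPXR controls and 9.33 ± 0.346 (SD, n = 5) in Co4, the C57BL control cohort of CITCO. It was lower by −3.39 ± 0.178 than the mean of the 5 C57BL CMC cohorts, with an adjusted p of 2.51e-27. Nr1i2, the gene of mouse PXR, had a mean of 4.02 ± 0.477 (SD, n = 5) and was lower by −3.48 ± 0.139, with an adjusted p of 5.96e-35. Against each cohort alone the differences ran from −3.61 to −3.15 for Nr1i3 and from −3.61 to −3.24 for Nr1i2. Where these probe sets lie relative to the replaced parts of the genes is not given in the sources used here. In all, 899 genes were higher and 679 lower in hCAR/hPXR livers than in the mean of the cohorts. The largest differences upward were in acute phase genes, whose products rise in blood during inflammation. Lcn2, which encodes an iron carrier-binding protein of innate immunity, was higher by 4.86 ± 0.768, Saa2 by 4.51 ± 0.850 and Saa3 by 3.61 ± 0.434, both serum amyloid A genes. The metallothionein gene Mt2 was higher by 3.60 ± 0.659 and the orosomucoid gene Orm2 by 3.43 ± 0.696. Cyp4a14, a PPARα target, was lower by −2.79 ± 0.640, Pdk4 by −2.16 ± 0.383 and Elovl3 by −2.00 ± 0.432. Among the single cohorts the differences in the acute phase genes were as low as 0.35 for Lcn2, 0.16 for Saa2 and 0.14 for Orm2, and Cyp4a14 ranged from −4.29 to 0.64. The count was 2729 against Co1, 4667 against Co2, 445 against Co3, 23 against Co4 and 1043 against Co5. With only the CMC controls in the fit 913 genes differed, and 957, 901 and 700 did without replicates 1, 3 and 4 of each of these groups. Strain and cohort could not be separated, since hCAR/hPXR controls came from 1 cohort.

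CITCO, an agonist of human CAR, was given to both strains at 10 mg/kg by intraperitoneal injection. In hCAR/hPXR livers, Cyp2b10, the cytochrome P450 gene used as the marker of CAR activity, rose 38.4-fold. Its mean log2 value was 11.89 ± 0.428 in treated and 6.62 ± 0.693 in control livers (SD, n = 5 each), a difference of 5.26 ± 0.467 with an adjusted p of 7.38e-14. Cyp2c55, another cytochrome P450 gene, rose by 2.75 ± 0.372 and Meig1, known from meiosis, by 1.41 ± 0.299. Mme, which encodes the peptidase neprilysin, rose by 1.22 ± 0.262, and Nr3c2, the mineralocorticoid receptor gene, by 0.93 ± 0.185. Il18bp, which encodes a protein that binds interleukin-18, fell by 0.92, the small heat shock protein gene Hspb8 by 0.83 and Ropn1l by 0.66. In these genes all 5 treated livers lay outside the range of the controls. Cyp3a11, the usual marker of PXR activity, rose by 0.27 ± 0.0514 with an adjusted p of 0.0039. Of 28 CAR targets measured, 5 rose, none fell and 23 did not pass, while 16 rose when adjusted over the list alone. The list moved up with an adjusted p of 2.95e-26 by camera and 3.53e-05 with an estimated correlation, and its members Gsta2 at 1.36 and Abcc4 at 1.24 did not pass. Of 12 PXR targets, 2 rose, Ces2a by 0.70 and Cyp3a11, and the same number rose when adjusted over the list alone, with adjusted p = 0.000469 and adjusted p = 0.0940 with an estimated correlation. Of 30 targets of NRF2, the transcription factor of the antioxidant response, 2 rose and 11 rose when adjusted over the list alone, including the glutathione transferase gene Gsta4 at 1.09. Its adjusted p was 1.63e-10, and adjusted p = 0.0732 with an estimated correlation. Of 25 acute phase genes none passed and 8 fell when adjusted over the list alone, with Lcn2 and Mt2 both at −2.71, and Mt2 at −3.30 without CITCO replicate 2. The acute phase list moved down with an adjusted p of 6.35e-16, and adjusted p = 0.156 with an estimated correlation. Its mean ran from 11.43 to 11.90 in single treated livers and from 12.18 to 13.34 in the controls, a high level described below. None of 19 macrophage markers passed, also when adjusted over the list alone, and they moved down with an adjusted p of 0.000347, and adjusted p = 0.580 with an estimated correlation. Acot1, at 1.35, and the proliferation gene Mki67, at −0.19, did not pass. In all, 14 genes rose and 4 fell, with 6 and 1 of them changed at least 2-fold. The count was 11 without CITCO replicate 2, 32 without control replicate 1, 8 without control replicate 3 and 7 without control replicate 4. Cyp3a11 did not pass without 2 of the 10 arrays, nor did Meig1, Mme and Il18bp without 4, Gsta4 without 5, Hspb8 without 7 and Ropn1l without 8.

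In C57BL livers given CITCO, 1 gene passed. Cyp2c29, a cytochrome P450 gene on the list of CAR targets, rose by 0.57 ± 0.109, from a mean of 12.79 ± 0.139 to 13.36 ± 0.105 (SD, n = 5 each), with an adjusted p of 0.0265. All 5 treated livers lay above the control range. Cyp2b10 differed by 0.42 ± 0.467, Cyp2c55 by 0.46 ± 0.372 and Cyp3a11 by 0.13 ± 0.0514, and none of them passed. Cyp1a2, a cytochrome P450 gene of central hepatocytes, stood at 0.61 ± 0.183 and did not pass. Of 28 CAR targets 1 rose, as it did when adjusted over the list alone, and 27 did not pass, among them Gsta2 at 0.62, Cyp2c37 at 0.57 and Cyp2c54 at 0.54. The list moved up with an adjusted p of 0.0023, and adjusted p = 0.469 with an estimated correlation. None of 25 acute phase genes passed, and 13 fell when adjusted over the list alone. The list moved down with an adjusted p of 6.65e-25 and of 0.0395 with an estimated correlation. Its members Lcn2 at −3.87, Mt2 at −2.92, Saa2 at −2.81 and Orm2 at −2.78 did not pass over all genes, and Saa2 stood at −2.22 without CITCO replicate 2. The mean of the acute phase list ran from 10.98 to 11.77 in single treated livers and from 12.03 to 13.19 in Co4. In the other C57BL control livers it ran from 10.04 to 11.84. The fall is thus one against a high control cohort and is not separated from the state of that cohort. Of 19 macrophage markers none passed, also when adjusted over the list alone, with Marco at −1.47 and Vsig4 at −1.01. They moved down with an adjusted p of 4.06e-06, and adjusted p = 0.473 with an estimated correlation. At an unadjusted p under 0.05, 874 genes differed. No gene passed without CITCO replicate 1, 2, 4 or 5 or control replicate 2, 4 or 5, and 2 passed without control replicate 1. With only these 2 groups in the fit the count was 0.

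The difference between the CITCO responses of the strains was tested gene by gene. Cyp2b10 responded more in hCAR/hPXR than in C57BL livers by 4.84 ± 0.660, with a 95% interval from 3.53 to 6.16 and an adjusted p of 3.03e-06, and was the 1 gene to pass. For Cyp2c55 the difference was 2.28 ± 0.526, from 1.24 to 3.33, with an adjusted p of 0.255. Cyp3a11 differed by 0.14 ± 0.0727, from −0.01 to 0.28, and Acot1 by 1.02 ± 0.637, neither passing. At an unadjusted p under 0.05, 367 genes differed. Across genes, which are not independent replicates, the fold changes of the strains had a Pearson correlation of 0.505 (jackknife SE 0.114). Co4 and the hCAR/hPXR controls, against which the treated groups were set, both had high acute phase genes, with list means of 12.48 and 12.62. With only these 4 groups in the fit 2 genes passed, and likewise 2 without treated hCAR/hPXR replicate 3.

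**Figure D1:**
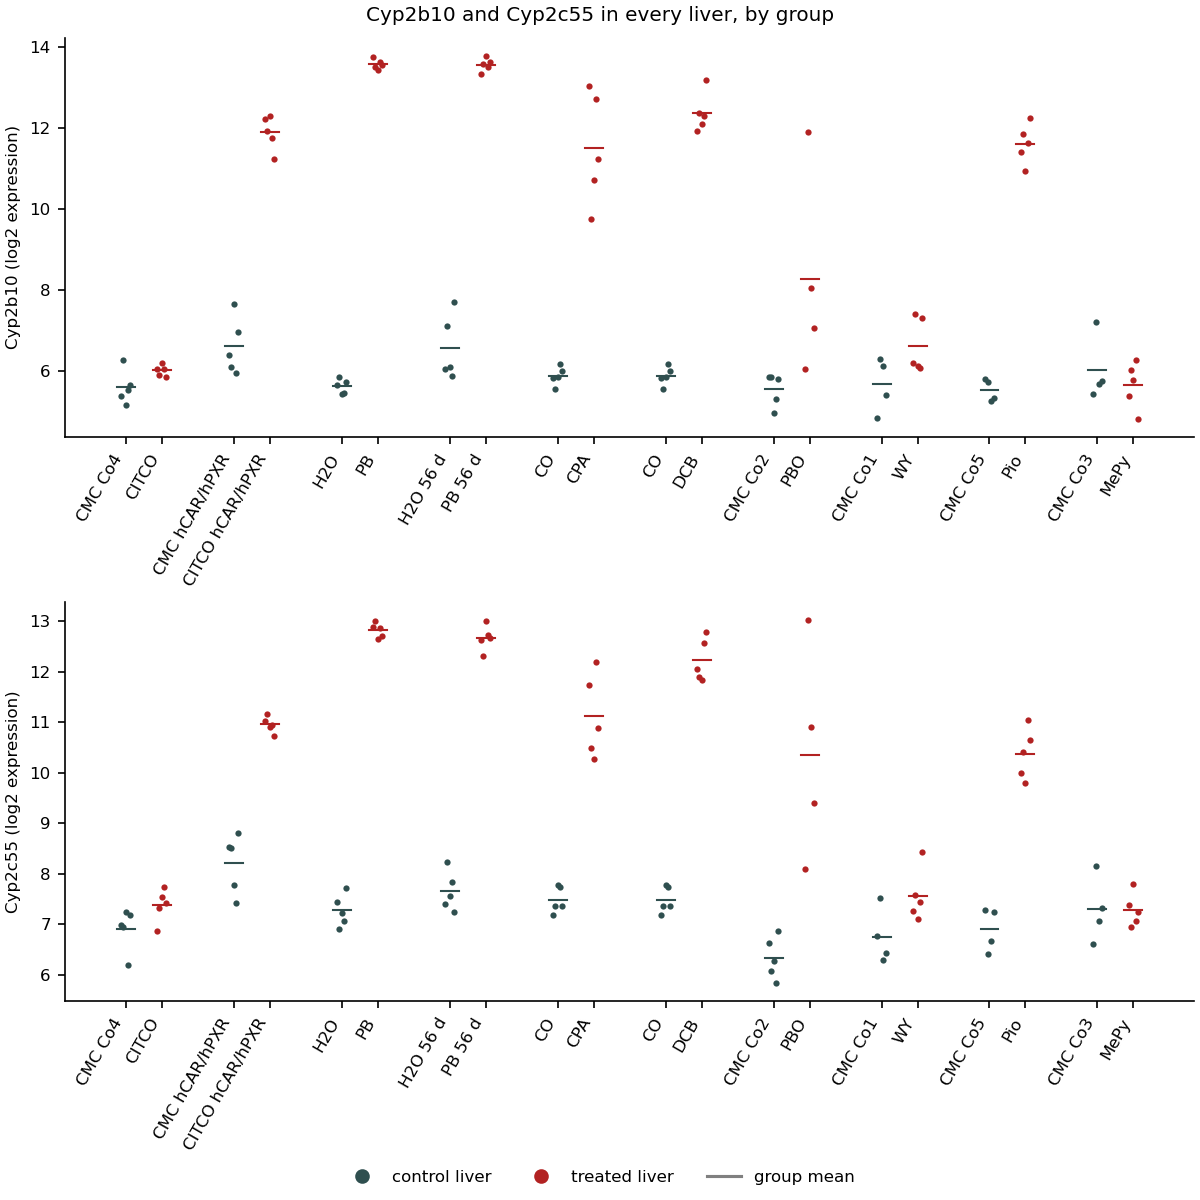
Log2 values of Cyp2b10 and Cyp2c55 in every liver (points) with the group mean (bar), treated groups (PB phenobarbital, CPA cyproterone acetate, DCB 1,4-dichlorobenzene, PBO piperonyl butoxide, WY Wy-14643, Pio pioglitazone, MePy methapyrilene) beside the control group named in their labels (CO corn oil). Cyp2b10 means are 13.57 after 28 days of phenobarbital, 11.89 after CITCO in hCAR/hPXR and 6.03 after CITCO in C57BL livers.

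Phenobarbital, an indirect activator of CAR and a promoter of liver tumours in mice, was given at 0.05% in drinking water. After 28 days Cyp2b10 rose 244-fold, from 5.64 ± 0.180 to 13.57 ± 0.120 (SD, n = 5 each), a difference of 7.93 ± 0.467 with an adjusted p of 8.07e-24. Cyp2c55 rose by 5.56 ± 0.372, Cyp2b9, a cytochrome P450 gene normally higher in females, by 4.54 ± 0.635, Gstm3 by 3.33 ± 0.326 and the efflux transporter gene Abcc4 by 3.07 ± 0.344. Serpina7, which encodes thyroxine-binding globulin, fell by 2.04, the small GTPase gene Rab30 by 1.29, the liver transcription factor gene Foxa3 by 1.22, Gem by 1.13 and the interleukin-6 receptor gene Il6ra by 1.11. All 5 treated livers lay outside the control range for these genes. Meg3, a noncoding RNA of the imprinted Dlk1-Dio3 cluster, rose by 1.38 ± 0.181 (adjusted p 6.36e-08), and its neighbours Rian, Mirg and Dlk1 did not pass. Gadd45b, a stress-inducible gene, rose by 1.27 ± 0.293, Cyp1a2 by 0.84 ± 0.183 and Cyp3a11 by 0.21 ± 0.0514. The antioxidant gene Nqo1 at 0.86, Ccnd1, the cyclin D1 gene, at −0.72 and Mki67 at 0.09 did not pass. Of 28 CAR targets 23 rose, 5 did not pass, and all 28 rose when adjusted over the list alone. The list moved up with an adjusted p of 2.11e-105 and of 2.71e-14 with an estimated correlation. Of 30 NRF2 targets 9 rose and 17 rose when adjusted over the list alone, including Gsta2 by 2.00 and the carbonyl reductase gene Cbr3 by 1.35. Of 12 PXR targets 5 rose and 10 rose when adjusted over the list alone, among them the transporter genes Slco1a4 by 1.45 and Abcb1a by 1.30 and the carboxylesterase gene Ces2a by 1.22, while Alas1 at 1.39 did not pass. With an estimated correlation the adjusted p was 0.0012 for the NRF2 and 1.11e-06 for the PXR list. Of 22 female-biased genes 3 rose and 6 rose when adjusted over the list alone, including Sult3a1 by 2.88 and Cyp2b13 by 2.08, with adjusted p = 0.298 with an estimated correlation. Of 42 PPARα targets 3 fell and 6 fell when adjusted over the list alone, with Cyp4a14 at −1.91, Fgf21 at −1.90 and Acot1 at −1.51 not passing. Their adjusted p was 1.63e-10, and adjusted p = 0.292 with an estimated correlation. In all, 104 genes rose and 72 fell, 42 and 7 of them at least 2-fold. With only these groups in the fit 332 passed, and the count was 108 without treated replicate 1, 97 without treated replicate 4, and 112, 88 and 113 without control replicates 1, 2 and 3. Without treated replicate 2 Cyp2b9 stood at 5.28 and Cyp4a14 at −1.24, without treated replicate 1 Cyp4a14 stood at −2.60, and without treated replicate 4 Sult3a1 stood at 2.24. Il6ra and Cyp2b13 did not pass without 8 of the 10 arrays, Abcb1a and Sult3a1 without 5, Slco1a4 and Cyp3a11 without 4 and Gadd45b without 2.

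After 56 days of phenobarbital Cyp2b10 rose 126-fold, by 6.98 ± 0.467 (n = 5 each), with an adjusted p of 1.86e-20. Cyp2c55 rose by 5.02 ± 0.372, Abcc4 by 3.49 ± 0.344, the cytochrome P450 gene Cyp2c65 by 3.21 ± 0.299 and Cbr3 by 3.12 ± 0.309. The retinol dehydrogenase family genes Rdh16f2 and Rdh9 fell by 1.19 and 0.94, the vasopressin receptor gene Avpr1a by 1.16, Tlcd2 by 0.93 and the corepressor gene Tle1 by 0.79. For these genes all 5 treated livers lay outside the control range. Meg3 rose by 1.43 ± 0.181 (adjusted p 2.18e-08), Gadd45b by 1.58 ± 0.293 and Cyp1a2 by 0.93 ± 0.183, and Cyp3a11, at 0.09, did not pass. Among 28 CAR targets 20 rose and 25 rose when adjusted over the list alone, and the list had an adjusted p of 1.04e-95 and of 1.25e-13 with an estimated correlation. Among these genes Cyp2b9 rose by 3.88, and by 5.38 without control replicate 5, whose value of 11.33 lay above all 5 treated livers at 8.67 to 9.78. It did not pass with only these groups in the fit, with an adjusted p of 0.196. Of 30 NRF2 targets 11 rose and 24 rose when adjusted over the list alone, including Gstm3 by 2.43, and Gsta2 at 1.13 did not pass. Of 12 PXR targets 4 rose, as when adjusted over the list alone, including Ces2a by 0.97, Abcc2 by 0.54 and Aldh1a1 by 0.48, and Alas1 at 0.74 did not pass. With an estimated correlation the adjusted p was 1.15e-06 for the NRF2 and 0.000775 for the PXR list. Of 23 genes of the urea cycle and amino acid breakdown 1 fell, Bhmt by 0.75, and 8 fell when adjusted over the list alone. This list moved down with an adjusted p of 2.84e-12, and adjusted p = 0.101 with an estimated correlation. None of 16 hepatocyte markers passed and 4 fell when adjusted over the list alone, with an adjusted p of 3.24e-07, and adjusted p = 0.0521 with an estimated correlation. In all, 78 genes rose and 25 fell, 31 and 3 of them at least 2-fold. Cbr3 stood at 2.47 without treated replicate 5. Rdh9 did not pass without 8 of the 10 arrays, Abcc2 without 9 and Tle1 without 6.

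Between 28 and 56 days of phenobarbital no gene's response differed by limma, and 879 did at an unadjusted p under 0.05. The response of Cyp2b10 at 56 days minus that at 28 days was −0.96 ± 0.660, with a 95% interval from −2.27 to 0.36. For Cyp2c55 it was −0.54, from −1.58 to 0.51, for Meg3 0.05, from −0.46 to 0.56, and for Acot1 1.82 ± 0.637, with an adjusted p of 0.740. Of the genes called at either time, 48 rose and 3 fell at both, where independent lists would share 0.446 and 0.0989. Across genes, which are not independent replicates, the Pearson correlation was 0.459 (jackknife SE 0.0679). The count was 1 without 56-day treated replicate 1 and 2 without replicate 2, and 2 and 1 without 28-day control replicates 4 and 5.

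Cyproterone acetate, a steroid antiandrogen known to activate PXR, was given by gavage at 160 mg/kg. Sult1e1, the estrogen sulfotransferase gene, rose by 6.39 ± 0.413, from 5 treated against 5 corn oil livers, with an adjusted p of 8.05e-22. Moxd1 rose by 5.65 ± 0.869, Cyp2b10 by 5.60 ± 0.467, Nebl by 3.94 ± 0.255 and Cyp2c55 by 3.63 ± 0.372. Mme fell by 2.93, the peroxisomal fatty acid transporter gene Abcd2 by 2.26, the circadian output gene Dbp by 2.24, the MHC class II gene H2-Aa by 2.24 and Ccnd1 by 2.21. All 5 treated livers lay outside the control range for these genes. Cyp3a11 rose by 0.33 ± 0.0514 and Gadd45b by 1.27 ± 0.293, while Cyp4a14 fell by 3.20 and the fatty acid synthase gene Fasn by 1.00. Of 28 CAR targets 12 rose, none fell and 16 did not pass, including rises of Gstm3 by 3.48 and Gstm2 by 2.67, and 13 rose and 3 fell when adjusted over the list alone. Of 12 PXR targets 6 rose, among them Ces2a by 1.85 and Cyp3a44 by 1.10, with Alas1 at −1.01 not passing, and 8 rose and 2 fell when adjusted over the list alone. The adjusted p with an estimated correlation was 0.0016 for the CAR and 0.0013 for the PXR list. Of 18 clock genes 9 fell and 2 rose, with falls of Ciart by 1.61, Per3 by 1.58 and Usp2 by 1.57, and 11 fell and 3 rose when adjusted over the list alone. Their adjusted p was 1.54e-05, and 0.0481 with an estimated correlation. Among control groups the mean of Dbp ran from 7.72 in Co5 to 11.90 in corn oil, and it was 9.66 after cyproterone acetate. A difference in time of day is thus not separated from the compound. Of 42 PPARα targets 12 fell, including Cyp4a31 by 1.32, and when adjusted over the list alone 14 fell and 1 rose, with adjusted p = 0.292 with an estimated correlation. Of 21 genes of fatty acid synthesis 7 fell and 9 fell when adjusted over the list alone, including the desaturase genes Fads2 by 1.36 and Fads1 by 0.92, with adjusted p = 0.230 with an estimated correlation. Of 27 interferon response genes 6 fell, including Usp18 by 1.69, Gbp3 by 1.29 and Ifi27l2a by 1.23, and 11 fell and 1 rose when adjusted over the list alone, with adjusted p = 0.303 with an estimated correlation. Of 20 stellate cell and fibrosis markers 2 fell, Postn by 1.76 and Col3a1 by 1.49, and 6 fell when adjusted over the list alone, with adjusted p = 0.469 with an estimated correlation. Endothelial and hepatocyte markers moved down too, with an adjusted p of 0.002 and 0.0292. With an estimated correlation these had adjusted p = 0.550 and 0.545. Of 25 acute phase genes 6 rose and 8 rose when adjusted over the list alone, including Lcn2 by 3.63 and Orm3 by 3.04, with adjusted p = 0.672 with an estimated correlation. The list rested on 2 livers: its mean was 12.91 and 12.77 in treated replicates 2 and 5, 10.91 to 11.07 in the other 3 and 10.58 to 11.68 in the controls. With replicate 2 and then replicate 5 left out of every group, controls included, the list did not pass, with an adjusted p of 0.151 and 0.647. In all, 476 genes rose and 492 fell, 70 and 79 of them at least 2-fold. With only these 2 groups in the fit 289 passed, and the count was 602 without treated replicate 2 and 633 without control replicate 2. Moxd1 and Cyp4a14 stood at 6.33 and −4.04 without treated replicate 1, Sult1e1 at 7.00 without treated replicate 3 and Lcn2 at 2.92 without treated replicate 5. Cyp4a14 stood at −2.54 without treated replicate 2 and did not pass. Fasn did not pass without 6 of the 10 arrays, Col3a1 without 7 and Lcn2 without 2.

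1,4-Dichlorobenzene, a solvent that causes liver tumours in mice, was given by gavage at 600 mg/kg and set against the same 5 corn oil livers. Cyp2b10 rose 88.9-fold, by 6.47 ± 0.467 (n = 5 each), with an adjusted p of 2.69e-19. Cbr3 rose by 5.35 ± 0.309, Cyp2c55 by 4.75 ± 0.372, Abcc4 by 4.68 ± 0.344 and the microsomal glutathione transferase gene Mgst2 by 3.27 ± 0.133. The chemokine gene Cxcl1 fell by 2.77, Susd4 by 2.31, the glutamate transporter gene Slc1a2 by 1.56, Lrg1 by 1.42 and Enho, which encodes adropin, by 1.40. In each of these genes the 5 treated livers lay outside the control range. Nqo1 rose by 2.00 ± 0.245 and Cyp1a2 by 0.76 ± 0.183, and Sqle, the squalene epoxidase gene of sterol synthesis, fell by 0.91. Cyp3a11 at 0.16 did not pass. Of 30 NRF2 targets 20 rose and 10 did not pass, including rises of Gstm3 by 3.06 and of the glutathione peroxidase gene Gpx2 by 2.38, and 25 rose when adjusted over the list alone. The 28 CAR targets measured included 19 that rose, also when adjusted over the list alone, and 9 did not pass. Of 12 PXR targets 3 rose, including Aldh1a1 by 0.76 and Ces2a by 0.52, and 4 rose when adjusted over the list alone. The adjusted p with an estimated correlation was 1.15e-06 for the NRF2, 4.39e-07 for the CAR and 0.0364 for the PXR list. Of 16 hepatocyte markers 8 fell and 9 fell when adjusted over the list alone, with Hnf4a, a master regulator of hepatocytes, at −0.54, Ahsg at −0.44 and the plasminogen gene Plg at −0.40. Their adjusted p was 1.23e-09 and 0.0163 with an estimated correlation. Of 8 oncofetal genes 3 rose, also when adjusted over the list alone, where 1 fell. They were Afp, the alpha-fetoprotein gene, by 3.12, Ly6d by 2.18 and the glypican gene Gpc3 by 1.10, with adjusted p = 0.0521 with an estimated correlation. Of 20 perivenous genes 6 fell and 1 rose, including falls of the glutamine synthetase gene Glul by 1.06 and Oat by 1.04. When adjusted over the list alone 6 fell and 3 rose, with adjusted p = 0.274 with an estimated correlation. Of 21 cholesterol synthesis genes 4 fell and 7 fell when adjusted over the list alone, with Sqle and Hsd17b7, at −0.70, among them, and adjusted p = 0.340 with an estimated correlation. Of 47 cell cycle genes Mcm6 rose, by 1.07, and 6 rose and 1 fell when adjusted over the list alone, with adjusted p = 0.521 with an estimated correlation. In all, 392 genes rose and 304 fell, 63 and 18 of them at least 2-fold. With only these 2 groups in the fit 320 passed, and the count was 394 without treated replicate 1. Sqle did not pass without 5 of the 10 arrays and Cxcl1 without 1.

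Cyproterone acetate and 1,4-dichlorobenzene shared their control livers. Both raised 111 genes and both lowered 99, an overlap that shared controls can enlarge by an amount not computed here, and 6 genes moved in opposite directions. Across genes, which are not independent replicates, the Pearson correlation was 0.442 (jackknife SE 0.116) and the covariance 0.0323. Simulated unchanged groups that shared a simulated control group had a mean correlation of 0.501, from 0.478 to 0.532. The observed correlation was no higher, but the simulated level follows from the equal group sizes. It therefore cannot decide whether the responses are alike. The simulated groups had a mean covariance of 0.0119, which the observed covariance exceeded by 0.0203. With the controls split between the compounds the correlation was 0.273 on average, from 0.182 to 0.337, and the covariance 0.0223. Phenobarbital at 28 days and 1,4-dichlorobenzene, which had different controls, both raised 48 genes, where independent lists would share 2.24.

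Piperonyl butoxide, an insecticide synergist that inhibits cytochrome P450 enzymes, was given intraperitoneally at 600 mg/kg. Cyp2c55 rose by 4.02 ± 0.394 (4 treated and 5 control livers), with an adjusted p of 4.18e-12. Nebl rose by 2.73 ± 0.270, Cyp2b10 by 2.70 ± 0.495, Gstm3 by 2.04 ± 0.346 and the fatty acid transporter gene Cd36 by 1.90 ± 0.340. The macrophage receptor gene Marco fell by 1.98, Enho by 1.5, the interferon-inducible GTPase genes Gbp2b and Irgm2 by 1.34 and 1.24, and Creld2, a gene of endoplasmic reticulum stress, by 1.30. All 4 treated livers lay outside the control range for these genes. Cyp2c55 ran from 8.10 to 13.03 in the treated livers (SD 2.12), and it stood at 4.78 and 3.13 without treated replicates 1 and 2. The Cyp2b10 values varied between treated livers, with an SD of 2.55 around a mean of 8.27, against 0.405 around 5.58 in controls. Without treated replicates 1 and 2 Cyp2b10 stood at 3.43 and 1.49. Cyp3a11 rose by 0.51 ± 0.0545 (adjusted p 1.22e-10). The aryl hydrocarbon receptor targets Cyp1a1 and Cyp1a2 rose by 2.09 ± 0.376 and 0.86 ± 0.194, with 2 and 4 treated livers above the control range, and Cyp1a1 stood at 2.85, 1.17 and 2.68 without treated replicates 1, 2 and 4. Of 9 targets of this receptor 2 rose and 7 did not pass. Their list did not pass by camera, with an adjusted p of 0.420, and adjusted p = 0.672 with an estimated correlation. Of 28 CAR targets 13 rose and 17 rose when adjusted over the list alone, including Gstt3 by 1.71. Of 12 PXR targets 5 rose and 6 rose when adjusted over the list alone, including Ces2a by 1.61 and Cyp3a44 by 1.16. The adjusted p with an estimated correlation was 1.32e-05 for the CAR and 4.98e-06 for the PXR list. Of 30 NRF2 targets 7 rose and 10 rose when adjusted over the list alone, including Abcc3 by 1.03 and the epoxide hydrolase gene Ephx1 by 0.89, with adjusted p = 0.0940 with an estimated correlation. Of 27 interferon response genes 2 fell, Igtp by 1.17 and Gbp3 by 1.09, and 5 fell when adjusted over the list alone, with adjusted p = 0.307 with an estimated correlation. Marker lists of 3 cell types moved down too. Of 16 hepatocyte markers 2 fell and 4 fell when adjusted over the list alone, with an adjusted p of 1.18e-06, and adjusted p = 0.0728 with an estimated correlation. Of 19 macrophage markers 1 fell and 2 fell when adjusted over the list alone, and of 9 neutrophil markers 1 fell, also when adjusted over the list alone. These had an adjusted p of 1.67e-05 and 0.0103, and adjusted p = 0.505 and 0.456 with an estimated correlation. The macrophage call was kept in 12 of 15 alternatives and the neutrophil call in 8 of 14. Of 42 PPARα targets 2 rose, Vnn1 by 1.58 and Aldh3a2 by 0.94, and 4 rose when adjusted over the list alone, with adjusted p = 0.672 with an estimated correlation. In all, 89 genes rose and 58 fell, 20 and 15 of them at least 2-fold. The count depended strongly on the arrays and the fit: it was 10 with only these groups in the fit, 231 after repeated quantile normalization, 2061 without the 3 arrays of low weight (an alternative chosen after seeing the data), 241 and 71 without treated replicates 2 and 3, and 221, 271 and 95 without control replicates 1, 2 and 3. Against all 5 C57BL CMC cohorts pooled, Igtp and Gbp3 stood at 0.05 and 0.26 and Vnn1 and Aldh3a2 at −0.16 and −0.61, each with the opposite sign. Lgals3, Camp, S100a8 and S100a9 turned upward there too, so that falls of cell type markers depend on the control cohort used. Marco did not pass without 6 of the 9 arrays, Gbp2b without 4, and Irgm2 and Creld2 without 2.

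Wy-14643, an agonist of PPARα, was given by gavage at 100 mg/kg. Cyp2b9 rose by 5.77 ± 0.674 (5 treated and 4 control livers), with an adjusted p of 3.51e-10. Fabp4, a fatty acid binding protein gene typical of adipocytes, rose by 5.14 ± 0.540, Rad51b by 3.93 ± 0.524, the lipoprotein lipase gene Lpl by 3.88 ± 0.456 and the desaturase gene Scd2 by 3.87 ± 0.528. Serpina12 fell by 7.06, the male-specific steroid dehydrogenase gene Hsd3b5 by 6.78, the organic anion transporter gene Slco1a1 by 4.42, Serpina4-ps1 by 4.22 and Ugt2b38 by 3.86. All 5 treated livers lay outside the control range for these genes. Of 42 PPARα targets 21 rose and 21 did not pass, with rises of the fatty acid oxidation genes Cyp4a31 by 3.53, Acot2 by 2.85 and Ehhadh by 2.58 and with Cyp4a14 at 2.29 not passing. When adjusted over the list alone 27 rose and 1 fell, with an adjusted p of 2.46e-21 and of 0.0489 with an estimated correlation. Acot1 rose by 2.29 ± 0.478. Of 21 PPARγ and adipocyte-type lipid genes 8 rose and 1 fell, also when adjusted over the list alone, with rises of the lipid droplet gene Cidea by 5.03 and Mogat1 by 3.35, and of Cidec by 1.41. Their adjusted p was 0.0016 with an estimated correlation. Of 19 male-biased genes 13 fell and 14 fell when adjusted over the list alone, with an adjusted p of 0.0248 with an estimated correlation. Of 22 female-biased genes 8 rose and 2 fell, with Abcd2 up by 2.70 and Lifr down at −1.99, and 9 rose and 2 fell when adjusted over the list alone. Its adjusted p was 9.44e-05, and adjusted p = 0.273 with an estimated correlation. Of 47 cell cycle genes 20 rose and 25 rose when adjusted over the list alone, including Mki67 by 1.72 ± 0.370 and Ube2c by 1.71, with adjusted p = 0.267 with an estimated correlation. Ccnd1 rose by 1.28 and Gadd45b by 1.06, while Cyp1a2 fell by 1.06. Of 8 oncofetal genes 4 rose, also when adjusted over the list alone, including Afp by 2.66 and Ly6d by 2.42, with adjusted p = 0.0277 with an estimated correlation and 0.107 on ranks. Of 21 cholesterol synthesis genes 12 rose, including Mvd by 1.15 and Pmvk by 1.01, and 13 rose and 1 fell when adjusted over the list alone, with adjusted p = 0.303 with an estimated correlation. Of 19 macrophage markers 10 rose and 11 rose when adjusted over the list alone, including Lgals3 by 1.94 and the complement gene C1qb by 1.70, with adjusted p = 0.303 with an estimated correlation. Of 25 acute phase genes 6 rose and 8 rose when adjusted over the list alone, including Mt1 by 3.63 and Lcn2 by 3.58, with adjusted p = 0.570 with an estimated correlation. The mean of this list was 12.75 and 11.89 in treated replicates 2 and 5 and 10.06 to 10.92 in the other 3. In all, 1010 genes rose and 926 fell, 251 and 87 of them at least 2-fold. With only these 2 groups in the fit 792 passed, and the count was 1192 without treated replicate 5 and 1222 without control replicate 2. Cidea stood at 6.20 and 4.36 without treated replicates 2 and 3, Mt1 at 4.31, 2.97 and 4.42 without treated replicates 1, 2 and 3, and Scd2 at 4.49 without treated replicate 1. Lcn2 stood at 4.52 without treated replicate 1, and at 2.58 and 2.93 without replicates 2 and 5, where it did not pass. Ccnd1 did not pass without 5 of the 9 arrays, Cidec without 4 and Gadd45b without 2.

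Livers labelled pioglitazone came from mice given this PPARγ agonist by gavage at 100 mg/kg, per the labels. In them Cyp2b10 rose 66.7-fold, by 6.06 ± 0.495 (5 treated and 4 control livers), with an adjusted p of 1.17e-15. Cyp2c55 rose by 3.48 ± 0.394 and Cyp2c29 by 0.81 ± 0.116, with all 5 treated livers above the control range. The fourth gene to pass was Tor3a, named after its values were seen, which fell by 0.71 ± 0.142. Fabp4 at −0.33, Cidec at −0.60, Acot1 at −0.67, Cyp4a14 at −1.48 and Cyp3a11 at −0.03 did not pass. Among the 28 CAR targets 3 rose, 25 did not pass, with Gstt3 at 1.10 and Cyp2c54 at 1.01, and 10 rose when adjusted over the list alone. The list moved up with an adjusted p of 6.39e-17 and of 0.0014 with an estimated correlation. None of 42 PPARα targets passed, with Fgf21 at −2.48 and Pdk4 at −1.10, and 4 fell when adjusted over the list alone, with an adjusted p of 1.08e-12 and adjusted p = 0.221 with an estimated correlation. None of 21 PPARγ and adipocyte-type lipid genes passed, also when adjusted over the list alone, with G0s2 at −1.41 and Plin4 at −0.89. This list moved down with an adjusted p of 0.0014, and adjusted p = 0.115 with an estimated correlation. None of 19 macrophage markers or 27 interferon response genes passed, also when adjusted over the list alone. Both lists moved up, with an adjusted p of 7.16e-06 and 0.000117, and adjusted p = 0.474 and 0.533 with an estimated correlation. The unadjusted p was under 0.05 for 1394 genes. The count was 11 with only these groups in the fit, 21 without treated replicate 3, and 11 and 15 without control replicates 1 and 3. Without control replicate 2 Plin4 stood at −0.30, Pdk4 at −0.41 and Fgf21 at −1.76, and Fgf21 stood at −3.16 without control replicate 1.

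Livers labelled methapyrilene came from mice given this antihistamine at 1000 ppm in food, per the labels. Their named control, Co3, is a CMC cohort with its dose given in mg/kg rather than in ppm of food. Vehicle and feeding therefore cannot be separated from the compound in this comparison. The serine protease inhibitor gene Serpinb1a rose by 1.99 ± 0.367 (5 treated and 4 control livers), with an adjusted p of 0.0010. Kbtbd11 rose by 1.84 ± 0.207, Cd36 by 1.76 ± 0.340, the pantetheinase gene Vnn1 by 1.64 ± 0.369 and Gprc5b by 1.58 ± 0.175. The mitochondrial carrier gene Slc25a25 fell by 1.13, Cyp3a25 by 0.57, Slc6a7 by 0.51, Paqr6 by 0.50 and Cyp2d10 by 0.30. All 5 treated livers lay outside the control range for these genes. Of 21 PPARγ and adipocyte-type lipid genes 5 rose and 16 did not pass, and 8 rose when adjusted over the list alone. Fabp4 rose by 3.37 ± 0.540 and the lipid droplet genes Cidea and Cidec by 3.11 ± 0.557 and 2.55 ± 0.440, with Lpl at 1.77 not passing. The list moved up with an adjusted p of 6.59e-11 and of 0.000114 with an estimated correlation. Fabp4 and Cidec lay above the control range in 4 of the 5 treated livers each. Cyp2b10 at −0.36, Cyp4a14 at 1.63 and Acot1 at 0.58 did not pass. None of 19 macrophage markers passed over all genes and 12 rose when adjusted over the list alone, with Marco at 1.35 and Vsig4 at 1.15. This list moved up with an adjusted p of 5.03e-09, and adjusted p = 0.303 with an estimated correlation. None of 25 acute phase genes passed, also when adjusted over the list alone, with Lcn2 at 2.46. It stood at 1.49 and 3.16 without treated replicates 2 and 1 and at 3.07 without control replicate 3. They moved up with an adjusted p of 6.25e-06, and adjusted p = 0.533 with an estimated correlation, with a list mean of 12.58 and 11.43 in treated replicates 2 and 5 and 10.57 to 10.94 in the other 3. In all, 27 genes rose and 6 fell, 15 and 1 of them at least 2-fold. The count was 4 with only these groups in the fit, 18 among genes above the median level, 15 without treated replicate 5, and 18, 21 and 16 without control replicates 1, 3 and 4. Fabp4, Cidea and Cidec stood at 4.09, 3.92 and 3.28 without treated replicate 4. Slc6a7 did not pass without 6 of the 9 arrays, Vnn1 and Cyp3a25 without 5, and Paqr6 and Cyp2d10 without 4.

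**Figure D2:**
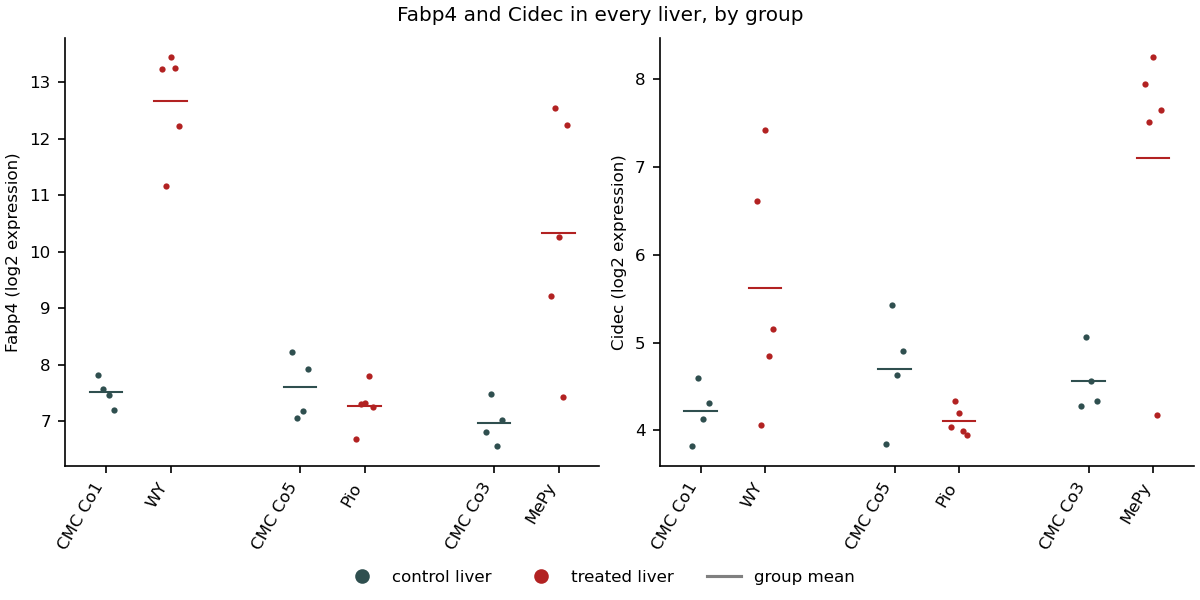
Log2 values of Fabp4 and Cidec in every liver (points) with the group mean (bar), for livers labelled Wy-14643, pioglitazone and methapyrilene and the control cohort named for each. Fabp4 differs from its control by 5.14, −0.33 and 3.37 in that order.

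Livers labelled Wy-14643 and pioglitazone, both PPAR agonists, were compared at the same labelled dose, 100 mg/kg by gavage for 28 days, each against its own control cohort. An exchange of the names pioglitazone and methapyrilene together with their cohorts stays open, as described below, and bears on this comparison. The responses differed in 549 genes, 286 with a larger and 263 with a smaller value under Wy-14643. Fabp4 differed by 5.48 ± 0.764, with a 95% interval from 3.96 to 7.00, Cyp2b9 by 5.27 ± 0.953, Cidea by 5.08 ± 0.788, Rad51b by 4.38 ± 0.741 and Cyp4a31 by 4.11 ± 0.507. Serpina12 differed by −6.79 ± 1.08, Hsd3b5 by −6.50 ± 1.26, Cyp2b10 by −5.11 ± 0.700, Slco1a1 by −4.33 ± 0.743 and Cyp2c54 by −4.30 ± 0.424. Cyp2c55 differed by −2.67 ± 0.558, Acot1 by 2.96 ± 0.676 and Mki67 by 1.86 ± 0.524, and all 3 passed. Cidec, at 2.00 ± 0.622 with an interval from 0.77 to 3.24, did not pass, nor did Cyp4a14, at 3.77 ± 1.22 with an interval from 1.34 to 6.21. No gene was called in both comparisons. With only 4 genes called for pioglitazone, independent lists would share 0.167 rising and 0.0509 falling genes, so this absence is uninformative. The Pearson correlation across genes, which are not independent replicates, was 0.0978 (jackknife SE 0.0898). Wy-14643 and methapyrilene both raised 20 genes, where independent lists would share 1.5. The difference of Cidea was 6.24 and 4.41 without Wy-14643 replicates 2 and 3. The count of differing genes was 364 without Co5 replicate 2.

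The control groups themselves differed. Acute phase genes had a list mean of 12.62 in hCAR/hPXR controls, 12.48 in Co4 and 11.51 in Co2, against 10.22 to 11.11 in the 6 other control groups. The median number of genes that differed between the 5 C57BL CMC cohorts was 1896.5 over their 10 pairs, from 15 between Co3 and Co5 to 5469 between Co2 and Co4. The first principal component, with 27.5% of the variance, had group means of −50.2 for piperonyl butoxide and −49.1 for its control Co2, and of 18.3 for corn oil and 19.7 for the water controls of 28 days. Piperonyl butoxide and Co2 livers also had the highest array medians, up to 5.34 and 5.36 against at most 5.29 in the other groups, so that a technical difference between arrays is not separated from this component. Dbp, which cycles over the day, had a mean of 7.72 in Co5, 9.82 in Co3 and 11.90 in corn oil controls, against 8.02 in livers labelled pioglitazone, 10.13 in those labelled methapyrilene and 9.66 after cyproterone acetate. Each treated group was compared with the control group its labels name, and pooled or other cohorts were used only where this is said. With only the cohorts compared in the fit the median was 1066, and it was 1031 and 910 without replicates 1 and 2 of each cohort.

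**Figure D3:**
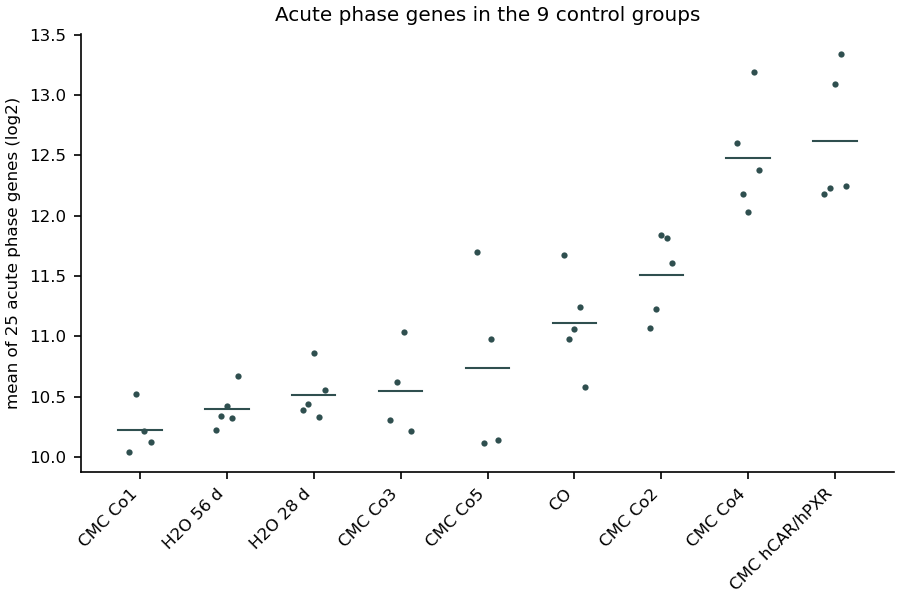
Mean log2 value of the 25 acute phase genes in every liver (points) of the 9 control groups, with the group mean (bar). Groups are ordered by their mean, from 10.22 in Co1 to 12.62 in hCAR/hPXR controls.

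**Figure D4:**
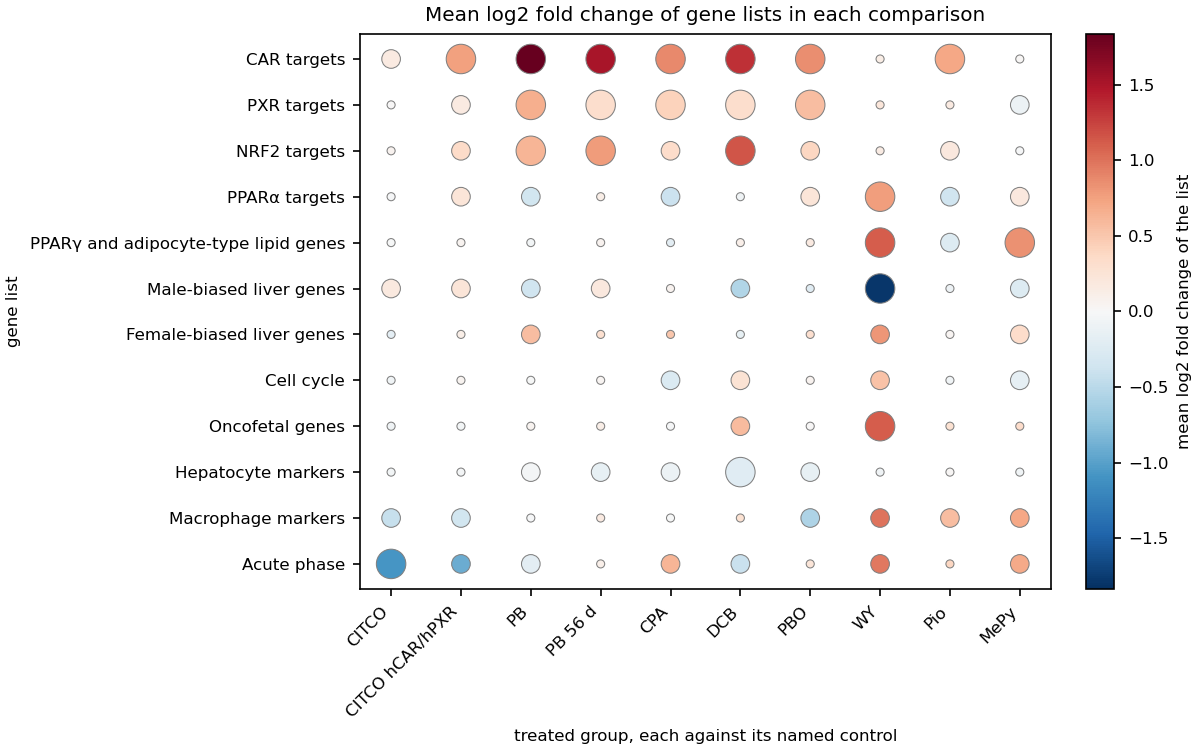
Mean log2 fold change (colour) of 12 gene lists in the 10 comparisons. Large points pass at an adjusted p below 0.05 with an estimated correlation, medium points with the preset correlation alone and small points with neither, and CAR targets have a mean of 1.84 after 28 days of phenobarbital.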

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

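The splits of the arrays and the comparison of acute phase genes with random lists were set before their results were seen, and the tests of exchanged labels, of a low control cohort, of the route and of single piperonyl butoxide arrays were chosen only afterwards. The comparison with random lists used the control groups of the route test, so its grouping was also chosen afterwards.

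The response to CITCO differed between the strains for Cyp2b10, by 4.84 on the log2 scale in the test of the difference itself. Single livers that stood far from the rest of their group were sought in 568 pairs of a named gene and a group, by the gap to the nearest other liver as a share of the group's range. This share passed Dixon's limit in 27 pairs, or 4.75%, and chance alone passes it in about 1 of 20 groups. The highest liver stood apart for Cyp2b9 in water controls of 56 days (replicate 5, share 0.943), Abcc3 and Cd36 after piperonyl butoxide (replicate 2, 0.929 and 0.858), Plin4 in Co5 (replicate 2, 0.902), Orm2 and Cyp1a2 in Co1 (replicates 2 and 3, 0.900 and 0.843) and Lpl in Co3 (replicate 2, 0.899). It also did for Oat and Lcn2 in corn oil controls (replicate 1, 0.886 and 0.719), Enho and Marco in Co2 (replicate 2, 0.790 and 0.740), Gsta2 after CITCO in C57BL livers (replicate 1, 0.781), and Abcc4 and Meg3 after 56 days of phenobarbital (replicates 5 and 1, 0.755 and 0.751). The lowest liver stood apart for Serpinb1a in Co3 (replicate 2, 0.877), Cidec and Paqr6 in livers labelled methapyrilene (replicates 4 and 5, 0.818 and 0.804), Cyp2b9 and Abcb1a in water controls of 28 days (replicate 4, 0.808 and 0.779), and Hnf4a after 1,4-dichlorobenzene (replicate 1, 0.787). It also did for Cyp7a1 after Wy-14643 (replicate 1, 0.848), Cyp1a2 and Cyp4a31 after Wy-14643 (replicates 5 and 2, 0.785 and 0.745), Rdh9 after 56 days of phenobarbital (replicate 5, 0.764), Gsta2 and Acot1 after 28 days of it (replicates 3 and 2, 0.754 and 0.713), and Cyp2c55 in Co4 (replicate 4, 0.719).

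Fabp4 and the lipid droplet genes Cidea and Cidec rose in livers labelled methapyrilene and did not pass in those labelled pioglitazone, and the PPARγ list had mean fold changes of 0.83 and −0.25 and medians of 0.23 and −0.22 (17 and 6 of 21 members above 0), a difference with a camera p of 3.83e-08 with an estimated correlation. An exchange of the treated arrays alone is argued against, because 9 of the 10 treated arrays lay nearer the control cohort their labels name, over the 15 genes that differed between these cohorts. Methapyrilene arrays lay at a log2 distance of 0.27 to 0.39 from Co3 and 0.84 to 1.14 from Co5. Pioglitazone arrays lay at 0.41 to 0.67 from Co5 and 0.48 to 0.85 from Co3. The argument thus rests mainly on the methapyrilene group, whose arrays share a cohort and are not independent. Low values in the methapyrilene controls are argued against, because the list still moved up against the other 4 C57BL cohorts, with a camera p of 0.0022. An exchange of both names together with their cohorts stays open: 244 genes at least doubled by Wy-14643 outside the PPARγ list had means of 0.42 (199 above 0) and 0.12 (154 above 0), and the difference had a p of 0.0701, which decides neither way. Fold changes of Wy-14643 had a Pearson correlation of 0.375 with methapyrilene and 0.0978 with pioglitazone. Wy-14643 and methapyrilene both raised 20 genes, where independent lists would share 1.5. It shared none with pioglitazone, for which only 4 genes were called. These values go with an exchange but were not tested for it. A response to methapyrilene itself or to feeding was not tested and may as well account for the pattern.

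Acute phase genes had list means of 11.51 to 12.62 in the 3 control groups named for compounds given intraperitoneally and of 10.22 to 11.11 in the 6 other control groups. The list differed between these groups by 1.61 on average, with a median of 0.63, at percentile 100 of 10000 random lists matched on level. The groups were set apart after their acute phase values were seen, so the percentile itself decides nothing. The random lists ran from −0.287 to 0.156, so a shift of that size in all genes of like level is argued against. An exact two-sided permutation test of 3 against 6 groups gave a p of 0.0119, the smallest that its 84 splits allow, so repeated injection could be a candidate explanation, as a hypothesis found and tested on the same data. The routes of the control mice are not given, and route and cohort cannot be told apart here, since each cohort is paired with compounds of 1 route and the cohorts differed in many genes. The treated livers of these compounds had means of 11.39 and 11.70 for CITCO in C57BL and hCAR/hPXR mice and 11.75 for piperonyl butoxide.

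Piperonyl butoxide livers had Cyp2b10 values of 6.07, 11.89, 8.06 and 7.07 for replicates 1 to 4, and 5.88 was the highest of the 5 controls. A control mislabelled as replicate 1 is argued against, because its mean over the 48 genes raised by both phenobarbital at 28 days and 1,4-dichlorobenzene was 9.11, above the highest control at 8.82 by more than the control SD of 0.086. That replicate 2 alone carries the induction is argued against as well, because 3 of the other 3 arrays lay above the controls by more than that SD, at 9.11, 9.41 and 9.31 against 9.91 in replicate 2. A difference in the dose that reached each liver could account for the range and was not tested.

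Each count was set against 100 splits of the compared arrays into groups of the same sizes, the real one included. Only the real split, 1 of 100, reached the count for CITCO in hCAR/hPXR mice (18 genes, highest other split 15) and phenobarbital at 28 and 56 days (176 and 25, 103 and 31). The same held for cyproterone acetate (968 and 309), 1,4-dichlorobenzene (696 and 346), Wy-14643 (1936 and 1727) and Wy-14643 against pioglitazone (549 and 122). It also held for the control cohorts (1896.5 and 234) and the list calls (132 and 112). The other splits had a median of 77 list calls, so a call with the preset correlation alone carries little weight. Few splits were as large for livers labelled pioglitazone, with 3 (4 genes, highest other 6), and methapyrilene, with 2 (33 and 35). These shares were not adjusted for the number of counts tested. Nor can splits tell an effect of a compound from another difference between its treated and control groups. Several of the highest other splits kept the real groups nearly whole. They exchanged 1 treated with 1 control liver for CITCO in hCAR/hPXR mice, phenobarbital at both times, cyproterone acetate and pioglitazone. For Wy-14643 treated replicate 1, and for livers labelled methapyrilene replicate 4, joined all controls. Such splits hold much of the real difference, so their counts are not those of chance alone. The other splits had medians of 1 for Wy-14643 and 0 for the rest of these. Chance could not be excluded for CITCO in C57BL mice, with 9 splits as large (1 and 19). For the strain difference in the CITCO response the splits bear on the count alone (1 gene, 5 splits as large, highest other 1) and not on Cyp2b10, whose difference of 4.84 had an adjusted p of 3.03e-06. For the phenobarbital times the count was 0 by limma (879 at an unadjusted p under 0.05, highest other split 2), so that all 100 splits were as large by construction and decide nothing. Chance could not be excluded either for the counts of piperonyl butoxide, with 30 (147 and 3048), and the untreated strains, with 5 (1578 and 2854), where splits that call so many genes point to a structure of the samples. Here too the splits do not bear on single genes. By limma Cyp2c55 had an adjusted p of 4.18e-12 after piperonyl butoxide, and Nr1i3 and Nr1i2 had 2.51e-27 and 5.96e-35 between strains. For piperonyl butoxide the highest split set treated replicate 2 and control replicates 3, 4 and 5 against the others.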

How the results depend on the processing

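The alternatives below were planned, except the removal of arrays of low weight, which was chosen after seeing the data, and the cause of a change was not tested unless stated. Over these alternatives 4261 values of called genes kept direction and call, 605 lost the call and 5 turned, and list calls kept 1610, lost 357 and turned 6. With only the compared groups in the fit, which leaves fewer arrays to estimate the spread, limma gave 0 genes for CITCO in C57BL mice, 896 at an unadjusted p under 0.05, and the counts became 332 for phenobarbital at 28 days, 289 for cyproterone acetate, 320 for 1,4-dichlorobenzene, 10 for piperonyl butoxide, 792 for Wy-14643, 11 for pioglitazone, 4 for methapyrilene, 2 for the strain difference, 1066 for the control cohorts and 913 for the untreated strains. With array weights they became 37 for CITCO in hCAR/hPXR mice, 840 and 295 for phenobarbital at 28 and 56 days, 68 for pioglitazone, 3 for the strain difference and 16 for the phenobarbital times. With all 5 C57BL CMC cohorts pooled as control, which adds cohort differences, they became 1896 for CITCO in C57BL mice, 4837 for piperonyl butoxide, 1058 for pioglitazone and 2785 for methapyrilene. Quantile normalization repeated gave 231 for piperonyl butoxide, 7 for pioglitazone and 1 for the phenobarbital times. For pioglitazone the mean of all probe sets gave 11 and every probe set 12, and for methapyrilene genes above the median level gave 18. Removing arrays of low weight gave 2061 for piperonyl butoxide, 112 of them called before, and 809 and 590 for cyproterone acetate and 1,4-dichlorobenzene.

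Replicate numbers did not pair the mice: deviations of same-numbered arrays correlated between −0.32 and 0.22, and in no comparison were all above 0.1. With the replicate block on the compared groups limma gave 0 genes for CITCO in C57BL mice, 875 at an unadjusted p under 0.05, and the counts were 370 for phenobarbital at 28 days, 196 for cyproterone acetate, 346 for 1,4-dichlorobenzene, 2 for piperonyl butoxide, 337 for Wy-14643, 17 for pioglitazone, 6 for methapyrilene and 221 for Wy-14643 against pioglitazone, and it moved no other count over 1.5 times. In no comparison did every array correlate best with the array of its own number.

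Leaving out 1 replicate at a time, counts ran from 0 to 2 for CITCO in C57BL mice, 7 to 32 in hCAR/hPXR mice, 88 to 162 and 71 to 90 for phenobarbital at 28 and 56 days, 602 to 1063 for cyproterone acetate, 394 to 935 for 1,4-dichlorobenzene, 71 to 271 for piperonyl butoxide, 1192 to 2238 for Wy-14643, 3 to 21 for pioglitazone and 15 to 39 for methapyrilene. They ran from 1 to 2 for the strain difference, 0 to 2 for the phenobarbital times, 364 to 767 for Wy-14643 against pioglitazone, 910 to 1693 for the control cohorts, 700 to 1530 for the untreated strains and 117 to 152 for list calls. For the list calls, the control cohorts and the untreated strains a replicate number was left out of all groups at once. List calls were 23 with an estimated correlation and 46 with fry. The correlation of the phenobarbital times was 0.199 by Spearman and 0.873 over called genes (0.416 to 0.484 leaving out arrays), and that of the CITCO strains 0.374 and 0.625 (0.409 to 0.516).

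Directions turned, with the adjusted p after the turn, for interferon genes after CITCO in C57BL mice without replicate 5 (0.965, range over replicates from 4.35e-06), stellate and B cell markers there without replicate 1 (0.464 and 0.924, ranges from 8.13e-08 and 0.000624), male-biased genes at 56 days of phenobarbital with array weights (0.818) and without replicate 5 (0.766, range from 0.0028), and cell cycle genes in livers labelled methapyrilene without replicate 2 (0.0015, the highest of a range from 3.5e-07). For piperonyl butoxide against the pooled cohorts Cyp4a14 stood at −2.01, Acot1 −1.89, Vnn1 −0.16, Aldh3a2 −0.61, Slc13a3 0.72, Igtp 0.051, Gbp3 0.26, Lgals3 1.15, Camp 0.60, S100a8 2.07 and S100a9 1.70. No control probe sets were used here, so the background of the arrays was not measured, and a fold change of a gene near the lower end of the signal is limited by it.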

Other observations

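The genes and livers below were chosen after their values were seen, from lists that were fixed earlier where a list is named, and no explanation was tested for them. After Wy-14643 (5 treated and 4 control livers) members of 3 further lists changed, and none of these lists passed with an estimated correlation. Of 27 targets of p53, 9 rose and 2 fell, and 10 rose and 2 fell when adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a rose by 1.40 ± 0.381, Sulf2 by 1.47 ± 0.232 and the antiproliferative gene Btg2 by 1.33 ± 0.444, while Gadd45a fell by 1.09. The list moved up with an adjusted camera p of 0.0018, and adjusted p = 0.0501 with an estimated correlation. Of 20 genes of bile acid synthesis and transport, 5 fell and 1 rose, including falls of the hydroxylase genes Cyp7b1 by 2.08 and Cyp39a1 by 1.15, and 7 fell and 2 rose when adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 1.08 and did not pass, and the list had adjusted p = 0.410 with an estimated correlation. Of 21 genes of fatty acid synthesis, 6 rose and 2 fell, with Fads2 up by 1.13 and falls of Elovl3 by 2.35 and Pklr by 1.22. When adjusted over the list alone 8 rose and 3 fell, with adjusted p = 0.672 with an estimated correlation.

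After 1,4-dichlorobenzene (5 livers in each group) 3 of 17 periportal genes fell, including Itih4 by 0.72 and the immunoglobulin receptor gene Pigr by 0.64, and 3 fell when adjusted over the list alone, with adjusted p = 0.389 with an estimated correlation. Of 18 clock genes 2 fell and 1 rose, with Ciart down by 1.07, and 9 fell and 2 rose when adjusted over the list alone, with adjusted p = 0.241 with an estimated correlation. The lactate dehydrogenase gene Ldha fell by 0.75, the 1 gene of 15 of gluconeogenesis and glycolysis to pass, and 4 fell when adjusted over the list alone, with adjusted p = 0.221 with an estimated correlation. After CITCO in hCAR/hPXR mice none of 20 stellate cell markers passed and 7 rose when adjusted over the list alone, with Acta2, the smooth muscle actin gene, at 1.57. That list had adjusted p = 0.303 with an estimated correlation.

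Some values were high or low in part of a group only. Lcn2 values were 12.61 and 13.64 in replicates 2 and 5 given cyproterone acetate and 9.02 to 9.42 in the other 3 livers, and after Wy-14643 they were 13.01 and 11.62 in replicates 2 and 5 and 5.24 to 8.18 in the others. Livers labelled methapyrilene had Lcn2 values of 12.83 and 10.95 in replicates 2 and 5, which also had the highest Fabp4 values, 12.54 and 12.25, and of 6.15 to 7.69 in the others. In livers labelled methapyrilene replicate 4 had a Fabp4 value of 7.44 and a Cidec value of 4.17, against 9.22 to 12.54 and 7.51 to 8.25 in the other 4. The water control of 56 days with a Cyp2b9 value of 11.33 had the highest Cyp4a14 value of its group, 13.33. Cyp4a14 reached 11.60 in replicate 2 of the hCAR/hPXR mice given CITCO, against 4.73 to 7.80 in the others.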
